A study of Rattus norvegicus with 60 samples.

How the data were processed

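The series compared gene expression in hepatocytes and in mesenchymal liver cells of Wistar rats treated with phenobarbital or with cyproterone acetate. The animals were 8 weeks old per the labels. Hepatocytes are the parenchymal cells of the liver. The mesenchymal fraction holds the other cells of the isolate, and the labels do not say which cell types it contains. RNA of each isolate (250 ng) was labelled and hybridised to an Affymetrix Rat Genome 230 2.0 array, 60 arrays in all. The fractions are written HC (hepatocytes) and MC (mesenchymal cells), the compounds PB (phenobarbital) and CPA (cyproterone acetate), and the vehicles H2O (drinking water) and CO (corn oil).

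The authors deposited log2 expression values made with RMA, which corrects the background, normalises the arrays to each other and summarises the probes of each probe set. The version of RMA was not given. No other scaling was applied to these values. Array medians ran from 3.25 to 3.39 in HC and from 3.39 to 3.44 in MC. Arrays of a group correlated across probe sets with r from 0.920 to 0.998, median 0.986, where probe sets are not independent replicates. The number of arrays limits the precision of every value.

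Of the 31042 probe sets, 20826 had exactly 1 gene symbol in the probe table, 436 had several and 9780 had none. Among those with 1 symbol, 20758 (99.7%) matched the reference gene table by identifier. Where a gene had several probe sets, the one with the highest mean over all 60 arrays stood for it, which left 14217 genes to test. No coordinates were used. The probe set 1371076_at lists the symbols Cyp2b2 and Cyp2b1, so its values are given by its ID and are not part of any gene list.

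Groups came from the sample labels, which name water as the control of PB and corn oil as the control of CPA. The treatment protocol instead says that rats given oil were the controls. The sample labels were followed. CPA and corn oil animals were labelled female. PB and water animals were labelled male, except replicate 3 of each such group at 24 h, labelled female. A group of corn oil controls at 24 h with the code CO_Co was described like the other, and what sets it apart is not stated. It served only in the comparison of the corn oil groups and in alternatives.

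The tests used R 4.3.3 and limma 3.58.1 (lmFit and eBayes). Each fraction was fitted with 1 mean per group plus a term for female sex, over all 30 arrays of the fraction. Differences between fractions used all 60 arrays with a term for sex within each fraction. P-values were adjusted by Benjamini and Hochberg over the 14217 genes, and a gene was called at an adjusted p under 0.05. A log2 fold change is treated minus control, given with its standard error (SE), and group means are given with the standard deviation (SD) between arrays. P-values measure the spread between arrays, since nothing in the labels says that replicates are separate animals.

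Besides the 8 treatment comparisons, limma tested the difference of effects between fractions (HC minus MC), between times (later minus 24 h) and between compounds at 24 h (PB minus CPA), the corn oil groups against each other (CO_Co minus CO), and vehicle HC against vehicle MC. Sex and vehicle differ between the compounds and cannot be told apart from the compound.

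There were 34 fixed lists, and 33 of them were tested. They were CAR/PXR-type phase I enzymes, phase II enzymes and transporters, AhR targets, PPAR-alpha targets, Nrf2 targets, cholesterol synthesis, fatty acid synthesis, bile acid genes, gluconeogenesis and fasting, G1/S and DNA replication, G2/M and mitosis, p53 targets, immediate early and heat shock, inflammatory cytokines and NF-kB, acute phase proteins, interferon response, growth factors and receptors, beta-catenin targets, matrix and stellate activation, glucocorticoid receptor targets, unfolded protein response, male-biased and female-biased liver genes, and markers of hepatocytes, Kupffer cells and macrophages, sinusoidal endothelium, stellate cells, cholangiocytes, T and NK cells, B cells, neutrophils, erythroid cells, and platelets and megakaryocytes. The list of sex chromosome genes served only to check the labels. A list needed at least 5 measured members. Lists share members, for example Nqo1 in AhR and Nrf2 targets, and the liver itself expresses most members outside the cell marker lists. Each list was tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. Fry tests whether the genes of a list move, on balance, one way, and it does not compare them with other genes. Marker list means per array were compared by two-sided exact permutation tests.

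The named genes followed a rule. For each treatment comparison it takes the 8 largest rises and the 8 largest falls among called genes in which every treated array lay on one side of every control array. For each list described it takes up to 4 called members with the largest change. For each difference it takes the 5 largest called genes per direction, and for the cell fractions the 3 brightest markers per cell type. Mki67 and Tnf are given in each treatment comparison. Symbols that are only LOC, RGD or MGC numbers were passed over.

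Same-numbered arrays counted as pairs where their deviations from group means correlated above 0.1 in every pair. Main fits were unpaired. Across genes, these correlations ran from 0.112 to 0.454 for PB in HC at 24 h, from 0.298 to 0.577 for PB in HC at 14 d, and from 0.36 to 0.720 for PB in MC at 14 d. The lowest was -0.0651 for PB in MC at 24 h, and the CPA comparisons did not reach the threshold in every pair.

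The pipeline was tested on effects planted in simulated noise. Its rates need not hold here, where arrays share structure. It recovered 86.6% of log2 changes of 1 with the design of PB in HC at 24 h, 74.6% with PB in MC at 14 d, 85.1% with CPA in HC at 24 h and 65.7% with CPA in MC at 6 d. At a log2 change of 0.5 it recovered 17.9%, 20.9%, 38.8% and 17.9%. For the fraction difference at 14 d of PB it recovered 58.2% of log2 differences of 1. No effect was called the wrong way. Unchanged genes made up 6 of 142 calls, 4 of 132, 10 of 158, 11 of 132 and, for the difference, 4 of 108.

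The alternatives were quantile normalisation within the fraction, leaving out the dimmest 40% of genes, the mean of all probe sets of a gene, only the groups compared, eBayes with trend and robust, array weights, a minimum of 2-fold, a block of replicate numbers, marker means as a covariate, the other corn oil group or both as control, only male arrays, and leaving out each array in turn. The groups, tests, lists, naming rule and these alternatives were fixed before the data were examined. Added after seeing the data were fits with no sex term, without the third replicate of both groups at 14 d, with all probe sets, and with a very similar pair of arrays averaged. Splits of the same arrays into other groups were fitted for every count, at most 100 draws per result. Values of individual probes were not used here.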

Results

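The 60 arrays were divided equally between hepatocytes (HC) and mesenchymal cells (MC), 30 arrays each. Each fraction held 9 groups: corn oil at 24 h (5 arrays), a further corn oil group at 24 h coded CO_Co (4), and 3 arrays each of corn oil at 6 d, cyproterone acetate (CPA, 100 mg/kg per day) at 24 h and 6 d, water at 24 h and 14 d, and phenobarbital (PB, 50 mg/kg per day) at 24 h and 14 d. Phenobarbital is a barbiturate that induces drug-metabolising enzymes, and cyproterone acetate is a steroidal antiandrogen and progestin that makes rat liver grow. Both promote liver tumours in rodents. The series asked how hepatocytes and the other liver cells each respond to them. Corn oil was given at 10 ml/kg.

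Without treatment, the fractions differed in 7634 of 14217 genes, 4128 higher in HC and 3506 in MC, or in 11982 with no sex term. That term, also in the fits below, rests on PB and water arrays at 24 h labelled female but male by Y gene level. Over the 18 vehicle arrays of each fraction, Clec4f, a lectin of Kupffer cells, stood at 5.69 ± 0.85 (SD) in HC and 12.01 ± 0.32 in MC on the log2 scale. Lyve1, a hyaluronan receptor of sinusoidal endothelium, stood at 5.41 in HC and 12.35 in MC, and the fitted difference was -7.36 (adjusted p = 4.74e-13). Other bright markers were higher in MC as well: Lyz2 (8.00 in HC, 10.33 in MC) and Cd5l (5.54, 11.85) of macrophages, Fcgr2b (5.64, 12.32) and Kdr (4.88, 11.63) of endothelium, and Gzma (2.60, 8.97), Prf1 (2.51, 8.55) and Lck (4.53, 7.34) of T and NK cells. So were markers of stellate cells, which store vitamin A and make collagen: Col3a1 (4.87, 8.74), Reln (4.15, 8.05) and Colec11 (4.81, 7.97).

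Transcripts of hepatocytes were abundant in both fractions. Alb, which encodes albumin, stood at 13.85 ± 0.02 in HC, at the top of the scale of these arrays, where differences are compressed, and at 13.46 ± 0.40 in MC. Ttr, which encodes transthyretin, stood at 12.97 ± 0.08 and 11.40 ± 1.02 (adjusted p = 0.0195), and Apoc3, an apolipoprotein, at 12.85 and 11.43 ± 0.91 (adjusted p = 0.0297). Among MC groups the mean of the hepatocyte marker list ran from 8.56 ± 0.80 in PB at 14 d to 10.29 ± 0.12 in water at 14 d. Of the cholangiocyte markers, Epcam was higher in HC (5.97 in HC, 2.15 in MC, adjusted p = 4.06e-11), while Tff3 and Spp1 were not called (adjusted p = 0.608 and 0.0685). Spp1 stood at 3.40 ± 0.24 in HC and 3.03 ± 0.23 in MC. The brightest markers of other blood cells were Hbb (3.73 in HC, 10.96 in MC), Hba-a3 (5.14, 7.79) and Alas2 (2.98, 4.48) of erythroid cells, Cd22 (5.17, 6.48), Fcrla (4.09, 6.17) and Blk (2.80, 5.26) of B cells, S100a8 (2.39, 4.50), S100a9 (2.20, 4.39) and Mmp9 (1.97, 4.22) of neutrophils, and Itga2b (5.02, 5.85), Itgb3 (3.02, 6.63) and Pf4 (3.70, 4.87) of platelets.

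**Figure D1:**
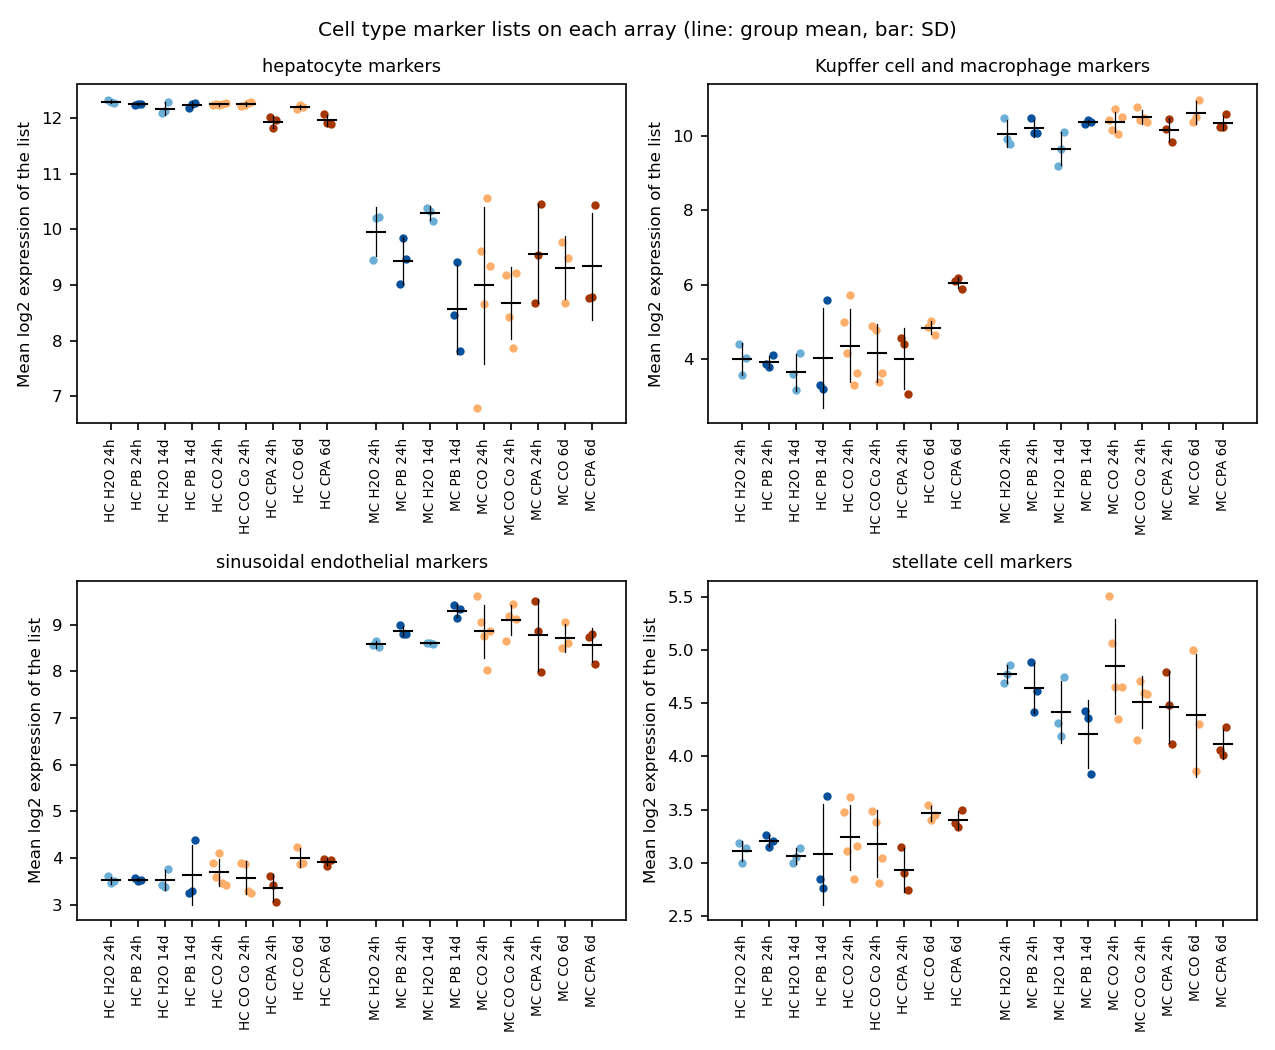
Mean log2 expression of 4 cell type marker lists (vertical axes) on each array (points) by group (horizontal axes), with hepatocyte arrays on the left and mesenchymal arrays on the right of each panel. Lines are group means and bars the SD; hepatocyte markers in MC had a mean of 8.56 in PB at 14 d and 10.29 in its water group.

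In hepatocytes 24 h after PB, Ugt2b1, a glucuronosyltransferase, rose by 3.44 (SE 0.35, adjusted p = 5.92e-06), from 7.54 ± 0.34 (n = 3) in water to 10.98 ± 0.19 (n = 3). Cyp2c6v1, a drug-metabolising P450, rose by 0.73 (SE 0.10, adjusted p = 0.00108) to 12.52 ± 0.12, and Hamp, which encodes the iron hormone hepcidin, rose by 1.23 (adjusted p = 0.0126). Tubb2a (2.57), Tnfaip8l1 (1.26) and Sphk2 (1.03) were the other rises. Klf10, a zinc finger factor induced by TGF-beta, fell by 1.37 (adjusted p = 0.0126), and Mpzl2 (-1.48), Hacl1 (-1.29), Bmp2k (-1.20), Acp3 (-0.88), Sugp2 (-0.78), Papss2 (-0.69) and Stim2 (-0.69) were lower too.

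Of 17 CAR/PXR-type phase I enzymes, 1 rose at 24 h over all genes and 7 rose adjusted over the list alone. The list was higher as a group (camera adjusted p = 7.68e-08, adjusted p = 0.0494 with an estimated correlation, median log2 change 0.39). Ces2c, a carboxylesterase, stood at 1.46 (adjusted p = 0.195). Of 26 phase II enzymes and transporters, 1 rose (2 adjusted over the list alone, adjusted p = 0.165 with an estimated correlation). Gsta3, a glutathione transferase, stood at 1.91 (adjusted p = 0.195). No member of the Nrf2 targets (0 of 15; 2 adjusted over the list alone; limma, Akr7a3 at 1.07, adjusted p = 0.0785, and Me1 at 0.88, adjusted p = 0.393) or of cholesterol synthesis (0 of 19; 0 adjusted over the list alone; Dhcr7 at 0.76 and Insig1 at 0.73, adjusted p = 0.443 and 0.537) was called. Tnf (-0.06) and Mki67 (0.24), which marks dividing cells, were not called.

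In all, limma called 14 genes (6 higher, 8 lower) in hepatocytes at 24 h of PB, and 1057 had an unadjusted p under 0.05. With array weights the count was 90. Each left-out array moved it, to 3, 4 and 8 without water replicates 1, 2 and 3 and to 5, 4 and 8 without PB replicates 1, 2 and 3. Ugt2b1 and Cyp2c6v1 were called each time, every other gene named was lost in at least 1, and only Ugt2b1 was called with replicate numbers as a block (1 gene, and 0 of the CAR/PXR-type list).

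In hepatocytes after 14 d of PB, Ugt2b1 was again higher, by 2.25 (SE 0.35, adjusted p = 0.00329), at 11.12 ± 0.61 against 8.87 ± 0.80 in water. App, the amyloid precursor protein, rose by 2.32 (adjusted p = 0.00329), Lpl, lipoprotein lipase, by 1.34 (adjusted p = 0.0128), and the citrate transporter Slc13a5 by 1.21 (adjusted p = 0.0357), along with Stau2 (1.17), Phospho2 (0.79) and Psmg4 (0.74). Ccdc141 fell by 2.42 (SE 0.35, adjusted p = 0.00329). Other members of the transporter family of Slc13a5 fell, the sulfate transporter Slc13a4 with -1.79 (adjusted p = 0.00450) and the dicarboxylate transporter Slc13a3 with -1.50 (adjusted p = 0.0128), and so did Ahi1 (-0.74).

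No CAR/PXR-type enzyme was called at 14 d over all genes (0 of 17; 4 adjusted over the list alone). Ces2c stood at 1.59 (adjusted p = 0.0982) and Cyp2c6v1 at 0.37 (adjusted p = 0.156). The median of this list was -0.02, its mean 0.28 and its test pointed up (adjusted p = 0.892 with an estimated correlation). Among phase II enzymes 1 rose (1 adjusted over the list alone, adjusted p = 0.892 with an estimated correlation), and Gstm2 stood at 0.73 (adjusted p = 0.298). Targets of beta-catenin, which mark hepatocytes around the central vein, had 0 of 12 called and 5 lower adjusted over the list alone. Glul, glutamine synthetase, stood at -2.22 (SE 0.51, adjusted p = 0.0915) and Axin2, a feedback inhibitor of Wnt signals, at -0.94 (adjusted p = 0.160). As a group this list was lower (median -0.54, camera adjusted p = 2.51e-05, adjusted p = 0.110 with an estimated correlation, fry adjusted p = 0.0306). Tnf (-0.21) and Mki67 (-0.27) were not called.

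For PB in hepatocytes at 14 d limma called 11 genes, 7 higher and 4 lower, and 1646 had an unadjusted p under 0.05. The count was 809 without water replicate 3, 26 without PB replicate 3, 2 without water replicate 1, 1 without PB replicate 2, and 523 without the third array of both groups. Without water replicate 3 the called members were 3 CAR/PXR-type, 6 phase II and 2 beta-catenin genes, without PB replicate 3 there were 2 CAR/PXR-type genes, and without water replicate 1 or PB replicate 2 no phase II gene was called. Only Ccdc141 was called in all leave-outs, and with replicate numbers as a block limma called 0 genes (1104 at an unadjusted p under 0.05), Ccdc141 having an adjusted p of 0.0588 and the phase II list 0 calls.

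In mesenchymal cells 24 h after PB, no gene was called by limma (0 of 14217), and 489 had an unadjusted p under 0.05. With array weights the count was 1140. Tnf, the cytokine of activated macrophages, stood at 1.44 (SE 0.49, adjusted p = 0.999) and Mki67 at 0.14. Immediate early and heat shock genes, which respond within minutes to stress, had 0 of 21 called and 0 adjusted over the list alone, with Klf6 at 0.75 and Dnajb1 at 0.73, and were higher as a group (median 0.75, camera adjusted p = 1.39e-11, adjusted p = 0.424 with an estimated correlation). Of 34 inflammatory cytokines and NF-kB genes none was called (2 adjusted over the list alone, adjusted p = 0.442 with an estimated correlation). The chemokine Ccl7 stood at 1.19 (adjusted p = 0.648) and the adhesion molecule Icam1 at 1.22. The hepatocyte marker mean was 9.44 ± 0.42 against 9.96 ± 0.44 (two-sided exact permutation p = 0.3, where 0.1 is the smallest possible). Without replicate 3 of water or of PB, 11 genes were called.

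In mesenchymal cells after 14 d of PB, genes of the hepatocyte were among those lower, and some genes of macrophages and of cell division among those higher. Sult1e1, estrogen sulfotransferase, fell by 3.54 (SE 0.43, adjusted p = 5.72e-05), from 10.89 ± 0.59 to 7.36 ± 1.38. Other large falls were Cyp2e1, a P450 that oxidises ethanol (-3.47, adjusted p = 0.00620), Cela1 (-3.41), Rgn (-3.38), Fmo1, a monooxygenase (-3.31), Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-3.27, SE 0.99), Slc13a4 (-3.23) and Fabp7 (-3.18). Tnf rose by 1.84 (SE 0.49, adjusted p = 0.0165), from 2.76 ± 0.58 to 4.59 ± 0.67. Chn1 (2.80), the activin subunit Inhbb (1.77), the peptide hormone Apln (1.69), Rfx4 (1.65), Hmcn1 (1.58), Enc1 (1.57, adjusted p = 0.00262) and the Notch regulator Nrarp (1.55) rose with it.

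Hepatocyte markers had 5 of 18 members lower (12 adjusted over the list alone), among them Asgr1, the asialoglycoprotein receptor (-2.49), Rbp4 (-2.23), Ahsg (-2.05) and Hpd (-2.0), and the list mean was 8.56 ± 0.80 against 10.29 ± 0.12 (two-sided exact permutation p = 0.1, the smallest possible). Beside this decrease, 10 of 14 male-biased liver genes fell (10 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.31e-09, adjusted p = 0.107 with an estimated correlation), such as the carrier protein Obp3 (-2.85), Cyp2a2 (-2.27) and the anion transporter Slc22a8 (-2.27). Also lower were 7 of 26 phase II genes (7 adjusted over the list alone; Sult1b1 -2.41, Gsta4 -2.39, Gstm2 -2.33), 7 of 19 cholesterol synthesis genes (9 lower and 1 higher adjusted over the list alone; Idi1 -2.44, Tm7sf2 -1.77, Pmvk -1.65, Fdps -1.48), 5 of 15 bile acid genes (6 adjusted over the list alone; Baat -2.84, Slc27a5 -2.76, Nr0b2 -2.51), and 1 of 19 acute phase genes (5 adjusted over the list alone; C3 -1.70, with Hpx at -1.83, adjusted p = 0.0511). Of 5 erythroid markers 2 fell (4 adjusted over the list alone; Alas2 -2.15, Ahsp -1.16). Each of these 5 lists had an adjusted p of 0.570 with an estimated correlation, as did the hepatocyte markers.

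Kupffer cell and macrophage markers had 5 of 15 members higher (12 adjusted over the list alone). Cd68 stood at 1.04, Adgre1, the macrophage antigen F4/80, at 0.94, Csf1r, the receptor of the macrophage growth factor, at 0.92 and Cybb at 0.76. The mean of the list was 10.37 ± 0.05 against 9.65 ± 0.45, that of sinusoidal endothelium 9.31 ± 0.14 against 8.60 ± 0.02, and that of stellate cells 4.21 ± 0.32 against 4.42 ± 0.29. Of 18 endothelial markers 1 rose (0 adjusted over the list alone), the clotting factor F8 (1.12), with Tek at 0.73 (adjusted p = 0.0529). Beside the lower hepatocyte markers, 6 of 21 immediate early genes rose (8 adjusted over the list alone, median 1.03), led by Klf6 (1.32), Ier2 (1.27), Nr4a1 (1.24) and Zfp36 (1.21). Of the inflammatory list, Tnf rose and Sod2 (-1.07) and the receptor antagonist Il1rn (-0.77) fell (1 higher and 2 lower of 34, the same counts adjusted over the list alone). Of 29 replication genes 8 rose and 1 fell (8 and 1 adjusted over the list alone). Pola1 stood at 0.94, Cdt1 at 0.93, Mcm6 at 0.92 and Mcm4 at 0.80. Of 35 mitotic genes 8 rose (8 adjusted over the list alone). Racgap1 stood at 1.37, Kif23 at 1.08, Bub1 at 0.92 and Hmmr at 0.88, and Mki67 stood at 0.75 (adjusted p = 0.102, or 0.0460 with the replicate block). With an estimated correlation these lists had an adjusted p = 0.570 (Kupffer, immediate early, mitosis), 0.588 (endothelium, replication) and 0.612 (inflammatory).

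For PB in mesenchymal cells at 14 d limma called 2675 genes, 1360 higher and 1315 lower, of which 735 changed at least 2-fold. The count was 388 without PB replicate 1, 778 without water replicate 1, 1469 without the third array of both groups, and 155 (60 higher, 95 lower) with the hepatocyte marker mean as a covariate. Without water replicate 1 or PB replicate 1 the Kupffer, immediate early, inflammatory, cholesterol, bile acid and endothelial lists had 0 calls each, replication had 2, mitosis had 4 and 2, and phase II 3 and 1. Leaving out water replicate 2 gave 3 phase II, 2 Kupffer, 2 immediate early, 4 mitotic and 4 erythroid genes, and leaving out water replicate 3 gave 4 phase II, 4 cholesterol, 10 Kupffer, 0 endothelial, 11 immediate early, 12 inflammatory and 5 mitotic genes. Without PB replicate 2 there were 2 cholesterol, 0 Kupffer and 16 mitotic genes, and without PB replicate 3 there were 4 phase II, 3 bile acid, 3 Kupffer, 3 immediate early, 4 replication, 5 mitotic and 1 erythroid gene. Erythroid markers had 0 calls without water replicate 1 or 3 or PB replicate 1 or 2, hepatocyte markers had 8 and acute phase genes 5 without PB replicate 2, and both had 0 without any other array. With that marker mean as a covariate phase II had 2 calls, bile acid genes 1, and the hepatocyte, cholesterol, acute phase, Kupffer, endothelial, erythroid, immediate early, inflammatory, replication and mitosis lists 0. Of the genes named for this comparison, Rfx4, Enc1, Sult1e1, Cyp2e1, Cela1, Rgn, Fmo1, Slc13a4, Pola1, Mcm6, Kif23, Hmmr, Obp3, Cyp2a2 and Slc22a8 were called in every leave-out, and the others were lost without water replicate 1 or PB replicate 1. With replicate numbers as a block the calls were 17 hepatocyte, 17 phase II, 15 cholesterol, 15 acute phase, 13 Kupffer, 11 endothelial, 4 erythroid, 16 immediate early and 21 inflammatory genes.

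In hepatocytes 24 h after CPA, the genes of cell division rose together. Mybl1, a transcription factor of the cell cycle, rose by 5.16 (SE 0.52, adjusted p = 3.91e-08), the cyclins Ccne2 by 4.31 and Ccna2 by 4.23, the replication factor Pclaf by 4.07 and Zfp367 by 3.98. Mki67 rose from 3.13 ± 0.41 (n = 5) to 6.53 ± 1.11 (n = 3), a change of 3.40 (SE 0.47, adjusted p = 2.69e-06). Of 29 replication genes 28 rose (29 adjusted over the list alone, adjusted p = 0.184 with an estimated correlation), such as Cdt1 (3.78), Mcm6 (3.57) and Tyms (2.84). Of 35 mitotic genes 34 rose (35 adjusted over the list alone, adjusted p = 0.184 with an estimated correlation), such as Ect2 (3.66), Cdk1 (3.61) and Racgap1 (3.6). Of 13 p53 targets 8 rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.184 with an estimated correlation). The cyclin-dependent kinase inhibitor Cdkn1a stood at 2.76, Mdm2, which degrades p53, at 2.73, Phlda3 at 2.12 and Aen at 2.0.

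Detoxifying enzymes rose in the same hepatocytes. Akr1b8, an aldo-keto reductase, rose by 4.09, Akr7a3 by 3.35, Srxn1 by 3.23 and Nqo1, a quinone reductase, by 2.22, and 10 of 15 Nrf2 targets rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.184 with an estimated correlation). Among 26 phase II genes 13 rose and 4 fell (14 and 4 adjusted over the list alone, adjusted p = 0.340 with an estimated correlation), led by Gstm3 (3.44), the transporter Abcc3 (2.68), Gstm1 (2.53) and Gsta3 (2.35). Of 17 CAR/PXR-type enzymes 6 rose and 1 fell (6 and 2 adjusted over the list alone, adjusted p = 0.643 with an estimated correlation). The epoxide hydrolase Ephx1 stood at 2.53, Ces2c at 1.65, Cyp3a23-3a1 at 1.44 and Aldh1a1 at 1.41. The chemokine Cxcl10 rose by 4.43 (SE 0.31, adjusted p = 3.69e-10), and Vxn by 4.07. Of 25 interferon response genes 10 rose (10 adjusted over the list alone, adjusted p = 0.562 with an estimated correlation). Isg15 stood at 2.38, Oas1a at 2.28, Usp18 at 1.68 and Irf7 at 1.43. Tnf stood at 0.06.

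Metabolic and secretory genes of the hepatocyte fell at 24 h of CPA. All but 1 of the 19 cholesterol synthesis genes fell (18, or 19 adjusted over the list alone). Hsd17b7 stood at -1.64, Insig1 at -1.63, Mvd at -1.53 and Tm7sf2 at -1.47. Of 18 fatty acid synthesis genes 10 fell and 1 rose (13 and 1 adjusted over the list alone). Thrsp stood at -2.37, Acss2 at -2.04, Fads2 at -1.80 and Acly at -1.71. In gluconeogenesis 7 of 11 fell (7 adjusted over the list alone). Sds stood at -2.73, Igfbp1 at -2.34, pyruvate carboxylase Pc at -2.16 and Irs2 at -1.17. Acute phase proteins had 13 of 19 lower and 1 higher (the same adjusted over the list alone). A2m stood at -2.06, Cp, ceruloplasmin, at -1.25, Itih4 at -1.12 and Serpina3n at -1.04. With an estimated correlation the adjusted p was 0.184 for cholesterol, fatty acid and acute phase genes and 0.189 for gluconeogenesis. Of 17 unfolded protein response genes 10 fell and 3 rose (the same adjusted over the list alone, adjusted p = 0.208 with an estimated correlation). Edem1 stood at -1.45, Hyou1 at -0.95, Sdf2l1 at -0.94 and Trib3 at 1.23. Of 12 female-biased genes 6 fell (6 adjusted over the list alone, adjusted p = 0.184 with an estimated correlation). The prolactin receptor Prlr stood at -2.08, Sult2a2 at -1.33 and Cyp17a1 at -1.17. Of 29 growth factors and receptors 6 fell and 3 rose (the same adjusted over the list alone, adjusted p = 0.202 with an estimated correlation). Egf stood at -2.09, Inhba at -2.0, Pdgfa at 1.67 and Nrg1 at 1.31. The largest falls of all were the nuclear receptor Esrrg (-4.37, SE 0.23, adjusted p = 1.71e-12), Abca8a (-4.21), Dpyd, which degrades pyrimidines (-4.21), Asph (-4.10), Reps2 (-3.62), Pcca (-3.55), carbonic anhydrase Car3 (-3.49) and Vps13b (-3.48). The hepatocyte marker mean was 11.94 ± 0.10 against 12.25 ± 0.02 (two-sided exact permutation p = 0.0179, the smallest possible, 0.444 adjusted over all marker tests).

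For CPA in hepatocytes at 24 h limma called 4963 genes, 3266 higher and 1697 lower, and 1260 changed at least 2-fold. Without CPA replicate 2 the interferon list had 3 calls and the unfolded protein response list 7, the latter having 8 without corn oil replicate 2, and of the named genes only Usp18, Sult2a2 and Cyp17a1 lost their call in a leave-out.

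In hepatocytes after 6 d of CPA, Cyp3a2, a male-specific P450 in adult rats, rose by 7.80 (SE 0.56, adjusted p = 2.34e-10), from 3.87 ± 1.41 to 11.67 ± 0.25. Gstp1, the placental glutathione transferase that marks altered rat liver cells, rose by 6.69 (SE 0.43, adjusted p = 4.17e-11), Akr1b8 by 7.28, the glutathione peroxidase Gpx2 by 6.42, the defensin Defb1 by 6.02, Adam8 by 5.52, Snx10 by 5.01 and Anxa2 by 4.82. A1bg, a female-specific plasma protein in rats, fell by 7.57 (SE 0.37, adjusted p = 1.93e-13), and Sult1c3 (-4.66), Mtmr7 (-4.06), Cpa1 (-3.95), Prlr (-3.72), metallothionein Mt2A (-3.55), Nfe2 (-3.36) and Cyp1a2 (-3.22) fell as well. Of 12 female-biased genes 6 fell (6 adjusted over the list alone, adjusted p = 0.0115 with an estimated correlation), among them Cux2 (-3.03), a female-specific factor in liver, and Sds (-2.77), which at 24 h in HC was lower in corn oil, labelled female (6.67), than in water (10.12). Of 14 male-biased genes 5 rose and 2 fell (6 and 3 adjusted over the list alone, adjusted p = 0.400 with an estimated correlation). Cyp2c13 stood at 2.88, Sult1e1 at 2.76 and Dhrs7 at 1.48.

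Genes of mitosis and detoxification were called at 6 d of CPA as well. Of 35 mitotic genes 33 rose (34 adjusted over the list alone, adjusted p = 0.0532 with an estimated correlation). Ccna2 stood at 4.23, Cdk1 at 3.93, Ccnb1 at 3.89, Ect2 at 3.74 and Mki67 at 2.61 (adjusted p = 0.000467). Of 29 replication genes 19 rose (21 adjusted over the list alone, adjusted p = 0.187 with an estimated correlation). Tyms stood at 2.91, Mcm6 at 2.31, Cdt1 at 1.62 and Mcm5 at 1.61. Of 13 p53 targets 8 rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.0417 with an estimated correlation). Cdkn1a stood at 3.90, Mdm2 at 2.58, Phlda3 at 2.5 and Ccng1 at 1.91. Of 15 Nrf2 targets 12 rose (12 adjusted over the list alone, adjusted p = 0.0272 with an estimated correlation). Akr7a3 stood at 4.09, Srxn1 at 3.24 and Nqo1 at 2.76. Of 26 phase II genes 15 rose and 1 fell (17 and 1 adjusted over the list alone, adjusted p = 0.0397 with an estimated correlation). Gstm3 stood at 3.35 and Abcc3 at 2.81. Of 17 CAR/PXR-type enzymes 6 rose and 3 fell (7 and 3 adjusted over the list alone, adjusted p = 0.532 with an estimated correlation). Cyp3a18 stood at 2.52, Aldh1a1 at 2.30 and Ces2c at 2.15.

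Lipid, bile acid and zonal genes of hepatocytes were lower at 6 d of CPA. Cholesterol synthesis had 17 of 19 lower (18 adjusted over the list alone, adjusted p = 0.0853 with an estimated correlation). Tm7sf2 stood at -2.80, Insig1 at -1.75, Ebp at -1.73 and Hsd17b7 at -1.67. Fatty acid synthesis had 12 of 18 lower (14 adjusted over the list alone, adjusted p = 0.0511 with an estimated correlation). Thrsp stood at -3.16, the desaturase Scd at -2.67, Fads2 at -2.18 and Acss2 at -1.92. Bile acid genes had 10 of 15 lower and 1 higher (11 and 1 adjusted over the list alone, adjusted p = 0.0397 with an estimated correlation). Slc27a5 stood at -2.97, Nr0b2 at -2.49, Cyp8b1 at -1.70 and the bile acid carrier Slc10a1 at -1.40. Of 21 PPAR-alpha targets 9 fell and 1 rose (the same adjusted over the list alone, adjusted p = 0.177 with an estimated correlation). Angptl4 stood at -2.54, Ehhadh at -2.28, Pdk4 at -1.75 and the thioesterase Acot1 at 4.02. Of 12 beta-catenin targets 8 fell (9 adjusted over the list alone, adjusted p = 0.0417 with an estimated correlation). Oat stood at -3.17, Lect2 at -1.30, Slc1a2 at -1.25 and Cyp2e1 at -1.22. Of 12 glucocorticoid receptor targets 7 fell (9 adjusted over the list alone, adjusted p = 0.0417 with an estimated correlation). The phosphatase Dusp1 stood at -2.53 and Gadd45g at -2.02. Of 15 Kupffer cell markers 4 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.582 with an estimated correlation). Cybb stood at 1.84, the leukocyte antigen Ptprc at 1.78, Adgre1 at 1.75 and Csf1r at 1.24. The mean of that list was 6.06 ± 0.16 against 4.85 ± 0.18 (two-sided exact permutation p = 0.1, the smallest possible). Tnf stood at -0.03.

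For CPA in hepatocytes at 6 d limma called 3548 genes, 2181 higher and 1367 lower, and 1182 changed at least 2-fold. Calls in the Kupffer list fell from 5 to between 1 and 3 without any 1 of the 6 arrays, cholesterol synthesis had 11 without corn oil replicate 2 or CPA replicate 2 or 3, and Pdk4, Mcm6, Sds, Cybb, Adgre1 and Csf1r lost their call in a leave-out.

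**Figure D2:**
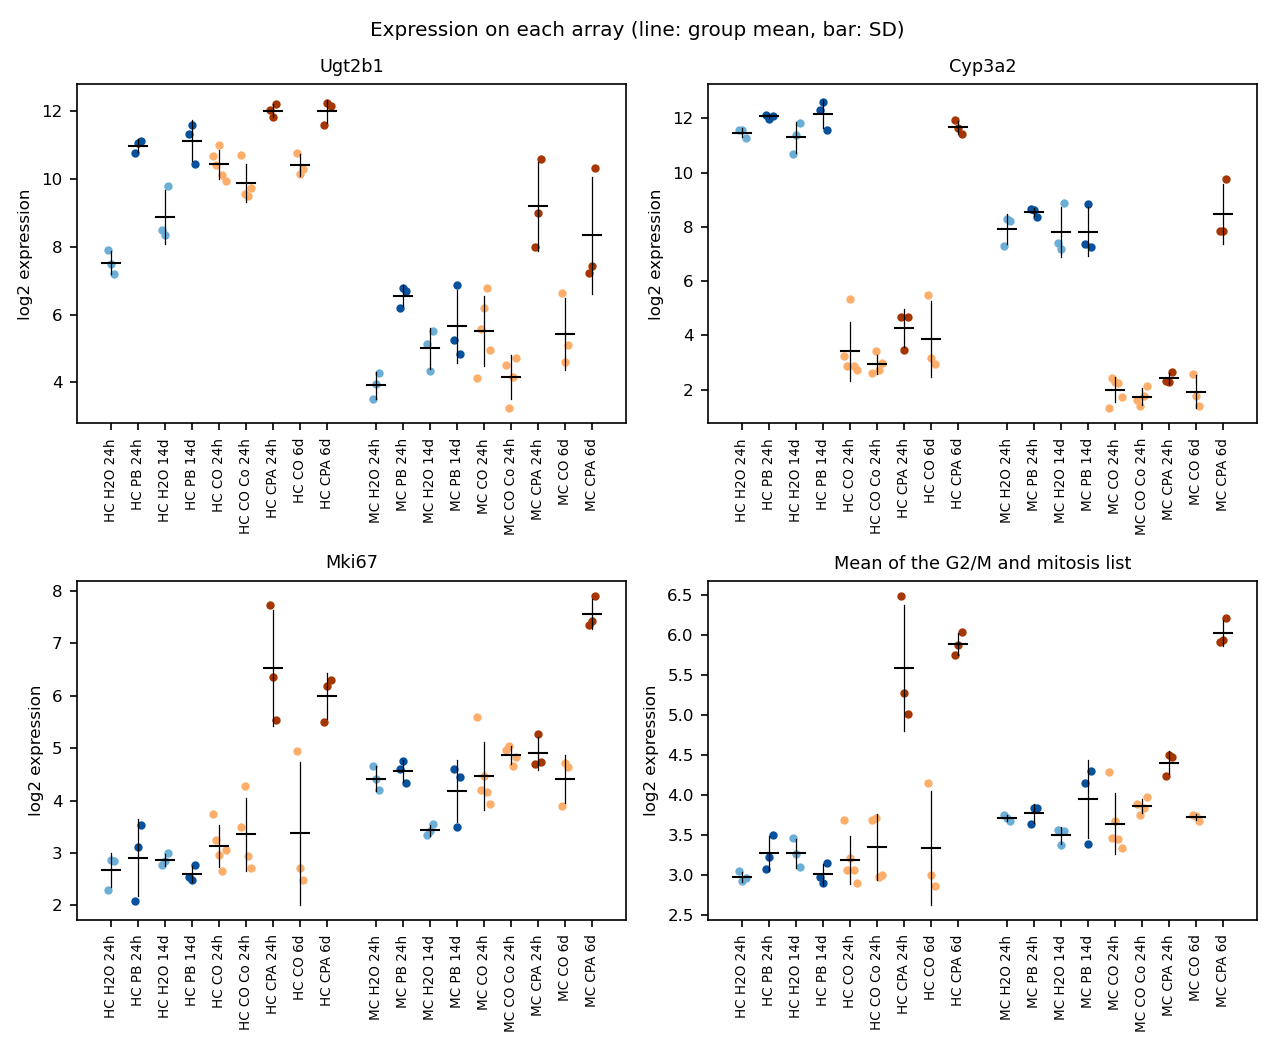
Log2 expression (vertical axes) of Ugt2b1, Cyp3a2, Mki67 and the mean of the mitosis list on each array (points) by group (horizontal axes), hepatocytes on the left and mesenchymal cells on the right of each panel, with lines for group means and bars for the SD. Mki67 in MC had a mean of 7.56 after 6 d of CPA and 4.41 in its corn oil group.

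In mesenchymal cells 24 h after CPA, detoxifying enzymes, cyclins and some p53 targets rose. Akr7a3 rose by 4.73 (SE 0.65, adjusted p = 0.000240), Cyp3a23-3a1 by 4.95 (SE 1.07, adjusted p = 0.0120), Ugt2b1 by 3.68, Gstm1 by 3.46, Gsta3 by 3.19 and Gstm2 by 3.13, and Vxn (3.70) and Mybl1 (3.63) rose as well. Dpyd fell by 2.85, and Lrat, which stores vitamin A as ester in stellate cells, by 1.64 (adjusted p = 0.00879). Sybu (-1.96), the retinoic acid hydroxylase Cyp26a1 (-1.84), Ppp2r2b (-1.35), Ube2e2 (-1.33), Plaat1 (-1.29) and Fggy (-1.21) were lower too. Of 17 CAR/PXR-type enzymes 4 rose (5 adjusted over the list alone, adjusted p = 0.401 with an estimated correlation). Ephx1 stood at 2.44, Ces2c at 1.32 and Alas1 at 1.21. Of 26 phase II genes 7 rose (9 adjusted over the list alone, adjusted p = 0.265 with an estimated correlation), and of 15 Nrf2 targets 7 rose (8 adjusted over the list alone, adjusted p = 0.0748 with an estimated correlation). Nqo1 stood at 2.12, Srxn1 at 2.04 and Gsr at 1.73. Replication had 12 of 29 higher (18 adjusted over the list alone, adjusted p = 0.0400 with an estimated correlation). Ccne2 stood at 1.96, Ccne1 at 1.57, Cdt1 at 1.52 and Rfc4 at 1.18. Mitosis had 13 of 35 higher (20 adjusted over the list alone, adjusted p = 0.140 with an estimated correlation). The kinetochore gene Spc25 stood at 2.52, Ccna2 at 2.03, Cdk1 at 1.65 and Cdca3 at 1.52. Of 13 p53 targets 3 rose (7 adjusted over the list alone, adjusted p = 0.0400 with an estimated correlation): Phlda3 (1.97), Aen (1.39) and Mdm2 (0.78). Beside these, the hepatocyte marker mean was 9.56 ± 0.89 (n = 3) against 9.0 ± 1.41 (n = 5, two-sided exact permutation p = 0.571), and Mki67 (0.43) and Tnf (0.47) were not called.

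For CPA in mesenchymal cells at 24 h limma called 394 genes, 342 higher and 52 lower, and 117 changed at least 2-fold. The count was 59 without CPA replicate 3, 62 without CPA replicate 2, 1059 without CPA replicate 1, 242 without corn oil replicate 3, 809 without corn oil replicate 4, and 6 with only these groups in the fit. It was 799 with the other corn oil group as control, 902 with both and 2586 with array weights. Without CPA replicates 2 and 3 in turn, the calls were 1 and 1 CAR/PXR-type, 4 and 3 phase II, 5 and 4 replication, and 3 and 4 mitotic genes; p53 had 1 without replicate 2 and 6 without replicate 1, Nrf2 had 4 without replicate 3, and CAR/PXR had 2 without corn oil replicate 1, 3 or 5. Akr7a3, Vxn, Mybl1, Gstm1 and Gstm2 were called in every leave-out.

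In mesenchymal cells after 6 d of CPA, genes of mitosis rose nearly as a block. Mki67 rose by 3.14 (SE 0.32, adjusted p = 7.02e-07), from 4.41 ± 0.46 to 7.56 ± 0.29 (n = 3 each), and Cdk1 by 3.46, Ccnb2 by 3.14 and Ccna2 by 3.13. Of 35 mitotic genes 33 rose (34 adjusted over the list alone, adjusted p = 0.000141 with an estimated correlation), and of 29 replication genes 20 rose (25 adjusted over the list alone, adjusted p = 0.000478 with an estimated correlation). Ccne2 stood at 1.98, Cdt1 at 1.68, Mcm5 at 1.55 and Mcm6 at 1.46. Cyp3a2 rose by 6.56 (SE 0.48, adjusted p = 1.03e-08), Akr7a3 by 5.11, Gpx2 by 4.08, Lpl by 4.33 (adjusted p = 0.000511), the macrophage elastase Mmp12 by 4.15, the fatty acid carrier Fabp4 by 3.70 and Inhbb by 3.67. A1bg fell by 5.74 (SE 0.73, adjusted p = 1.15e-05), the chemokine Cxcl12 by 3.05 (SE 0.48), and Sult1c3 (-3.27), Cpa1 (-2.99), Cyp2c7 (-2.91), Akr1b7 (-2.81), Mylk3 (-2.08) and Vipr1 (-2.03) were lower too.

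Of 15 Nrf2 targets 6 rose at 6 d in these cells (10 adjusted over the list alone, adjusted p = 0.0307 with an estimated correlation). Nqo1 stood at 2.40, Akr1b8 at 1.73 and Srxn1 at 1.62. Of 17 CAR/PXR-type enzymes 4 rose and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.514 with an estimated correlation). Aldh1a1 stood at 3.25 and Ephx1 at 2.43. Of 26 phase II genes 4 rose (8 adjusted over the list alone, adjusted p = 0.336 with an estimated correlation): Gstm1 (3.02), Ugt2b1 (2.90), Gstm2 (2.26) and Gstm3 (1.88). Of 13 p53 targets 1 rose (2 adjusted over the list alone, adjusted p = 0.336 with an estimated correlation), Cdkn1a (2.12, adjusted p = 0.0380), and Mdm2 stood at 0.72 (adjusted p = 0.0847). Of 34 inflammatory genes 2 rose (3 adjusted over the list alone, adjusted p = 0.730 with an estimated correlation), Ccl7 (1.59) and Il1rn (1.19), and Tnf stood at 1.59 (adjusted p = 0.114). The hepatocyte marker mean was 9.34 ± 0.96 against 9.31 ± 0.57 (two-sided exact permutation p = 1). Carried hepatocyte RNA stays open for the enzymes all the same, since Cyp3a2 rose and A1bg fell in hepatocytes too at 6 d.

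For CPA in mesenchymal cells at 6 d limma called 335 genes, 304 higher and 31 lower, and 212 changed at least 2-fold. Nrf2 had 3 calls without CPA replicate 3, and phase II had 2 without it, 7 without corn oil replicate 1 and 1 without corn oil replicate 2 or 3. Cdkn1a, and with it the p53 count, was lost without each array but corn oil replicate 1, and Sult1c3, Cpa1, Akr1b7, Vipr1, Aldh1a1, Gstm1, Ugt2b1, Gstm2, Akr1b8 and Il1rn lost their call in a leave-out. Arrays 1 and 2 of this CPA group were closer to each other than any other mesenchymal pair (root mean square difference 0.168, against a median of 0.450). The labels do not say whether they come from 1 isolate, and with the pair averaged as 1 array 279 genes were called. The count was 139 without the dimmest 40% of genes and 1560 with array weights.

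**Figure D3:**
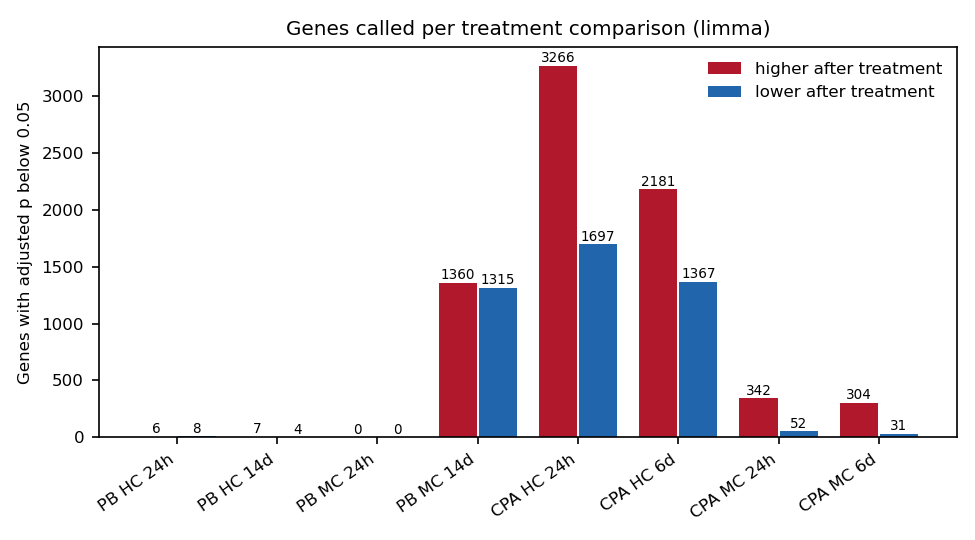
Number of genes with an adjusted p under 0.05 (vertical axis, linear) in each treatment comparison (horizontal axis), with bars for genes higher and lower after treatment. The bars run from 0 for PB in MC at 24 h to 3266 higher and 1697 lower for CPA in HC at 24 h.

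The difference of effects between the fractions was tested for each treatment, as HC effect minus MC effect. At 24 h of PB limma called 0 genes (646 at an unadjusted p under 0.05), or 1 gene without replicate 3 of water or PB in HC. At 14 d of PB 1561 genes differed (1006 with a higher, 555 with a lower effect in HC). Higher were Thrsp (3.55, SE 1.17, with 0.82 in HC and -2.74 in MC), Inmt (3.55), Poteml2 (3.50), Cela1 (3.41) and Fabp12 (3.31). These fell in MC, where falls went with less hepatocyte RNA. In the other direction stood Glul (-2.52, SE 0.55, adjusted p = 0.00342; -2.22 in HC, 0.30 in MC), Chn1 (-2.96), Ccdc141 (-2.18), Sv2b (-2.10) and Ston2 (-2.09). This count was 641 without PB replicate 1 and 1008 without water replicate 1 of MC, 976 and 1039 without water replicates 1 and 2 of HC, and 982 without PB replicate 3 of HC, and Thrsp, Chn1 and Ston2 lost their call in a leave-out.

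At 24 h of CPA 1274 genes differed between the fractions (939 with a higher, 335 with a lower effect in HC). Cxcl10 rose in HC (4.43) and stood at -0.23 in MC (difference 4.65, SE 1.0, adjusted p = 0.00147), and Akr1b8 (3.69), Racgap1 (2.99), Mki67 (2.97, SE 0.58, adjusted p = 0.000429) and Trim59 (2.90) also had the higher effect in HC. Abca8a (-3.75), Cyp3a23-3a1 (-3.51; 1.44 in HC, 4.95 in MC), Myo1d (-3.24), Vps13b (-3.23) and Nucb2 (-3.21) had the lower effect in HC. At 6 d of CPA 697 genes differed (470 and 227), with Gstp1 at 6.32 (SE 0.59, adjusted p = 3.03e-10; 6.69 in HC, 0.37 in MC), Akr1b8 at 5.55, Adam8 at 4.74, the developmental factor Sox4 at 4.70 and Snx10 at 4.49, against Inhbb at -3.44 (SE 0.55, adjusted p = 3.46e-05; 0.23 in HC, 3.67 in MC), Lpl at -3.35, the imprinted gene Mest at -3.34, Rasd1 at -3.20 and the fatty acid receptor Cd36 at -3.17. The count at 24 h was 724 without CPA replicate 2 of HC, and Cyp3a23-3a1, Mest and Rasd1 lost their call in a leave-out.

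Longer treatment changed the effect of CPA in hepatocytes in 2187 genes (1003 with a higher, 1184 with a lower effect at 6 d than at 24 h). Cyp3a2 (6.95), Gstp1 (6.41), Defb1 (5.23), Sox4 (4.51) and Esrrg (4.40, adjusted p = 4.42e-09; -4.37 at 24 h, 0.02 at 6 d) had the higher effect at 6 d. A1bg (-6.53), Oat (-3.13), Cux2 (-2.97), Ccne2 (-2.85; 4.31 at 24 h, 1.46 at 6 d) and Gadd45b (-2.70, lost in a leave-out) had the lower one. In mesenchymal cells 76 genes differed between the times of CPA (72 and 4), with Cyp3a2 at 6.14, Lpl at 4.70, Mmp12 at 4.65, Pcdh17 at 3.62 and Pimreg at 3.25, against A1bg at -5.76, Vxn at -3.48, Dnajb2 at -1.15 and Sgf29 at -0.87. That count was 48 without corn oil replicate 1 or 2 at 6 d, and Lpl, Dnajb2 and Sgf29 lost their call in a leave-out. For PB 5 genes differed between the times in HC: Slc13a5 (2.22), Klf10 (2.20, adjusted p = 0.00379; -1.37 at 24 h, 0.83 at 14 d), Psmg4 (0.95), Ccdc141 (-2.67) and Slc13a3 (-1.98), each lost in a leave-out. The HC count was 0 without replicate 3 of water or PB at 24 h, 3 and 2 without replicate 2 of water and PB at 24 h, 2 and 10 without replicates 2 and 3 of PB at 14 d, and 290 without replicate 3 of water at 14 d. In MC 2 genes differed, Obp3 (-2.28, adjusted p = 0.00118) and Pdzph1 (-1.73, adjusted p = 0.00105), and the count was 8, 6 and 4 without water replicate 3 at 14 d, PB replicate 2 at 14 d and PB replicate 1 at 24 h.

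At 24 h the effects of PB and CPA differed in 3097 genes of hepatocytes (980 with a higher, 2117 with a lower effect of PB). Ccne2 (-4.77; -0.46 with PB, 4.31 with CPA), Mybl1 (-4.59), Cxcl10 (-4.51), Vxn (-4.35) and Akr1b8 (-4.07) had the lower effect under PB, and Abca8a (4.20), Dpyd (4.13), Esrrg (4.13), Asph (4.09) and the tight junction gene Cldn1 (3.76; 1.25 with PB, -2.51 with CPA) the higher one. After quantile normalisation the split was 1145 higher and 1453 lower. In mesenchymal cells 15 genes differed (1 and 14), the amino acid transporter Slc7a5 (1.39) against Vxn (-3.71), Mybl1 (-3.66), Gstm3 (-2.84), Spc25 (-2.45) and Pclaf (-2.43). The MC count was 341 without CPA replicate 1, 44 and 27 without corn oil replicates 4 and 1, 6 without water replicate 1 or PB replicate 2, and 7 without CPA replicate 2 or 3, corn oil replicate 2 or 5, water replicate 2 or PB replicate 1, and Slc7a5 and Pclaf lost their call in a leave-out. Sex, vehicle and compound change together here.

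The corn oil groups at 24 h differed from each other in 10 genes of hepatocytes, 1 higher and 9 lower in CO_Co. Stac3 was higher (2.15, SE 0.36, adjusted p = 0.00916; 6.37 ± 1.24, n = 4, against 4.22 ± 0.44, n = 5), and the pantetheinase Vnn1 (-2.84), Fabp2 (-1.60), Eci1 (-1.52), Aig1 (-1.28) and Acot2 (-1.18) were lower. The count was 17, 6, 2, 5 and 5 without corn oil replicates 1 to 5 and 23, 1, 1 and 1 without CO_Co replicates 1 to 4, and Vnn1 alone was called in every leave-out. In mesenchymal cells limma called 0 genes (394 at an unadjusted p under 0.05), or 1 without corn oil replicate 1.

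Across genes, which are not independent replicates, the effects of CPA at 24 h and 6 d correlated with Pearson r = 0.55 (Spearman rho = 0.47) in HC and r = 0.42 in MC. Of the CPA rises in HC, 1289 were called at both times (501 by chance) and 638 falls were (163 by chance), while 168 genes were called in opposite directions. Effects of CPA in HC and MC correlated with r = 0.54 at 24 h and at 6 d, with 324 shared rises at 24 h (78.6 by chance) and 238 at 6 d (46.6 by chance). PB effects at 24 h and 14 d correlated with r = 0.60 in MC and 0.00 in HC, and PB effects in HC and MC with r = 0.18 at 24 h and 0.01 at 14 d.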

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

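In this part the tests of the weighed patterns were chosen after the results were seen, as were their bounds and the bound set for the splits of the arrays, while the difference tests were planned.

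Tested directly, the fractions' effects differed in 1561 genes at 14 d of PB, 1274 at 24 h and 697 at 6 d of CPA. For PB, less hepatocyte RNA in MC stays open. Between treatment times the effects differed in 2187 genes for CPA in hepatocytes, 76 for CPA in mesenchymal cells, 5 for PB in hepatocytes and 2 for PB in mesenchymal cells. Outside the gene table stood probe set 1371076_at, which the probe table gives to several genes. In hepatocytes it was higher by 5.07 (SE 0.53, adjusted p = 1.07e-05) at 24 h of PB, with 12.28 ± 0.17 against 7.22 ± 0.35 (n = 3 each). There it was also higher by 4.49 at 14 d of PB (adjusted p = 0.000231), 3.87 at 24 h of CPA (adjusted p = 8.19e-07) and 2.81 at 6 d of CPA (adjusted p = 0.000362). In mesenchymal cells it was not called (2.70 and 2.07 for PB, 2.15 and 2.36 for CPA; adjusted p = 0.999, 0.0631, 0.118 and 0.162).

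Single arrays stood apart from their group in 3 of 112 Dixon tests, where chance gives 5.6. The platelet marker mean was 3.34 in corn oil replicate 4 of hepatocytes at 24 h (3.57 to 3.64 in the others). The cholangiocyte marker mean was 2.44 in corn oil replicate 4 of mesenchymal cells at 24 h (2.09 to 2.17 in the others). Ube2e2 stood at 5.46 in CO_Co replicate 2 of mesenchymal cells (4.56 to 4.65 in the others).

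After 14 d of PB, mesenchymal arrays had 1315 genes lower and 1360 higher than water. The falls went with less hepatocyte RNA: 93.9% of the falling genes had a higher level in hepatocytes than in mesenchymal cells in water at 24 h, against 60.03% of all genes and at most 64.9% in 10000 random lists, and in the vehicle groups 755 of them were called higher and 20 lower in hepatocytes. The test was first run on water at 14 d (70.8% against 54.9%) and moved because those arrays are part of the comparison. For the rises, a relative gain of all other cell types alike was not settled. The erythroid list was taken for this test because it had called falls here, so its gap cannot decide the question. The Kupffer marker mean gained 2.05 (SE 0.56) over the erythroid mean, with PB arrays at 4.44 to 5.10 and water arrays at 2.17 to 3.83. Over the stellate mean it gained 0.92 (SE 0.26; 5.88 to 6.52 against 4.89 to 5.46), though many stellate markers lie near background, and over well expressed members (15 and 5) the gain was 0.85 (SE 0.42; 2.90 to 4.07 against 2.28 to 3.03, overlapping). A gain of Kupffer and endothelial cells, whose marker means rose by 0.72 and 0.70, stays open. Stress during isolation also stays open, since the immediate early list had a median of 1.03 (fry adjusted p = 0.0729) in these cells and 0.12 (fry adjusted p = 0.681) in hepatocytes, as does an action of PB on the mesenchymal cells themselves.

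After 6 d of CPA, 33 mitotic genes were higher in mesenchymal cells. RNA of dividing hepatocytes carried into the fraction was argued against: the levels of these genes in mesenchymal cells were a median of 0.08 above those in treated hepatocytes, 19 of the 33 were above and the lowest was at -1.13, while hepatocyte markers lay at -3.19 to -1.52 on the same arrays. Other dividing cells that entered the fraction stay open, since the largest median change among 9 other cell type lists was 0.23 and their smallest fry adjusted p was 0.204. Among marker means, neutrophils (0.40) and cholangiocytes (0.31) were higher and B cells (-0.47) lower with all arrays apart (each two-sided exact permutation p = 0.1, the smallest possible). A candidate explanation is division of cells of the fraction itself under CPA, which the arrays did not test.

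After 24 h of CPA, 18 genes of the xenobiotic lists were higher in mesenchymal cells. Hepatocyte RNA carried into the fraction stays open for the set. The levels of these genes were a median of -1.69 relative to treated hepatocytes (-3.84 to -0.59), while hepatocyte markers had an offset of -2.38, and 0 of the 18 rose more on the linear scale than in hepatocytes. Of the 18, 1 was called with the larger effect in mesenchymal cells and 1 in hepatocytes. Of all 342 rises in mesenchymal cells, 324 were also called higher in hepatocytes, against 23.0% of all genes. A response of mesenchymal cells themselves stays open beside it, since both could add to the same arrays.

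Other splits of the same arrays were fitted for every count. With 6 arrays only 10 splits exist, too few for a share under 0.05. The real count and the highest other were 14 and 1 for PB in hepatocytes at 24 h (1 of 10 as large), 11 and 1559 at 14 d (6 of 10), 0 and 0 for PB in mesenchymal cells at 24 h (10 of 10), 2675 and 381 at 14 d (1 of 10), 3548 and 4 for CPA in hepatocytes at 6 d (1 of 10), and 335 and 0 for CPA in mesenchymal cells at 6 d (1 of 10). The split with 1559 genes set the third arrays of both groups apart with 1 more array, which points to a structure of the samples. Of the 4 splits that part every pair, 1, 2 and 1 gave as many genes for PB in hepatocytes at 24 h, at 14 d and PB in mesenchymal cells at 14 d, with highest others of 0, 19 and 0.

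Chance was excluded for CPA in hepatocytes at 24 h (4963, highest other 1678, 1 of 56 splits), the time difference of CPA in hepatocytes (2187, highest other 3446, 2 of 100), the compound difference in hepatocytes (3097, highest other 3059, 1 of 100) and in mesenchymal cells (15, highest other 18, 2 of 100), the corn oil groups in hepatocytes (10, highest other 16, 3 of 100) and the cell fractions (7634, highest other 58, 1 of 100). The share was not under 0.05 for CPA in mesenchymal cells at 24 h (394, highest other 2792, 6 of 56), where a split with so many genes points to a structure of the samples. Over all splits drawn, nor was it for the difference between fractions at 14 d of PB (1561, highest other 2280, 8 of 100), 24 h of CPA (1274, highest other 3093, 6 of 100) and 6 d of CPA (697, highest other 1897, 10 of 100). The same held for the time difference of PB in hepatocytes (5, highest other 645, 17 of 100) and mesenchymal cells (2, highest other 1416, 9 of 100), and that of CPA in mesenchymal cells (76, highest other 779, 14 of 100). However, some of these splits left a pair of groups intact, which keeps a treatment effect and does not measure chance. Without them, a count added later, the share was under 0.05 for the fractions at 6 d of CPA (1 of 84, the real one) and for the times of PB (1 of 78, the real one) and CPA (4 of 86) in mesenchymal cells. It was still not under 0.05 for the fractions at 14 d of PB (4 of 80) and 24 h of CPA (5 of 99) and for the times of PB in hepatocytes (11 of 85). Where the real count was 0 every split is as large by construction, so the splits tested nothing for PB in mesenchymal cells at 24 h, the fractions at 24 h of PB (0, highest other 1, 100 of 100) and the corn oil groups in mesenchymal cells (0, highest other 491, 100 of 100).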

How the results depend on the processing

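The fits without a sex term, without the third arrays, with all probe sets and with averaged arrays were chosen after the results were seen. No called named gene reversed its direction under any alternative run. Of the counts under alternatives other than leaving out an array 119 stayed within 1.5 times and 41 did not, and of those with an array left out 178 did and 60 did not. Of 390 called named genes 232 were called under every alternative, while 158 lost the call in at least 1. Of the counts of called list members 527 stayed within 1.5 times and 120 did not, and with an array left out 326 did and 98 did not. Without the dimmest 40% the mitosis list had 16 calls for CPA in hepatocytes at 24 h and 6 d and 15 in mesenchymal cells at 6 d, where fewer of its genes were tested. With only the groups compared in the fit, no list had more than 1 call for CPA in mesenchymal cells at 24 h. Of 64 set tests 45 lost their call with an estimated correlation. None of the 12 Pearson correlations across genes moved by 0.1 or more without the dimmest genes. Those of PB in hepatocytes at 24 h with 14 d (-0.002 to 0.046) and of PB at 14 d in hepatocytes with mesenchymal cells (0.007 to -0.003), both near 0, changed sign. Quantile normalisation moved no median of all genes by more than 0.1. It moved the share of higher effects from 31.6% to 44.1% for the compound difference in hepatocytes (1145 higher, 1453 lower) and from 73.7% to 62% for the fractions at 24 h of CPA (666 higher, 409 lower). Signal near background and 3 arrays per group limit what could be called. Unless said otherwise, the cause of a shift was not tested.

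A minimum of 2-fold, stricter by construction, left 9 genes for PB in hepatocytes at 24 h, 735 for PB in mesenchymal cells at 14 d, 1260 and 1182 for CPA in hepatocytes at 24 h and 6 d, and 117 and 212 for CPA in mesenchymal cells. Array weights gave 90, 106, 1140 and 4093 for PB (hepatocytes at 24 h and 14 d, mesenchymal cells at 24 h and 14 d) and 2586 and 1560 for CPA in mesenchymal cells at 24 h and 6 d. With only the groups compared in the fit, which leaves fewer arrays to estimate the spread, the counts were 2 for PB in hepatocytes at 24 h, 0 at 14 d (limma) and 6 for CPA in mesenchymal cells at 24 h. For PB in hepatocytes at 14 d the count was 19 after quantile normalisation, 21 without the dimmest 40%, 21 with the mean of probe sets, 20 with trend and robust, 21 with all probe sets and 523 without the third arrays, and the last gave 1469 in mesenchymal cells. Only arrays labelled male gave 8 genes for PB at 24 h in hepatocytes and 11 in mesenchymal cells. The hepatocyte marker mean as a covariate gave 3 genes for PB in mesenchymal cells at 24 h and 155 at 14 d, where the marker differs between the groups.

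For CPA in mesenchymal cells at 24 h, the other corn oil group as control gave 799 and both gave 902. Leaving out the dimmest 40%, with fewer genes tested, gave 139 for CPA in mesenchymal cells at 6 d, 13 for its time difference, 1 for that of PB in mesenchymal cells and 2 for the compound difference in mesenchymal cells. The last was 8 after quantile normalisation and 6 with water arrays 1 and 2 averaged. The mean of probe sets gave 1 gene for the fractions at 24 h of PB. Without a sex term the time difference of PB in mesenchymal cells was 1 and the cell fractions differed in 11982 genes.

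With a block of replicate numbers PB gave 1 and 0 in hepatocytes at 24 h and 14 d. In mesenchymal cells PB gave 0 (1463 at an unadjusted p under 0.05) and 3932. CPA gave 3519 and 3058 in hepatocytes and 11 and 197 in mesenchymal cells at 24 h and 6 d. Calls the block changed in comparisons with pairs stand beside them. For the fractions the block gave 0 (837 at an unadjusted p under 0.05), 2177, 1643 and 974 genes at 24 h and 14 d of PB and 24 h and 6 d of CPA, and 8172 without treatment. Same-numbered hepatocyte and mesenchymal arrays correlated above 0.1 in 7 of 9 groups (lowest 0.0856 in corn oil and 0.0469 in CPA at 6 d).

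Leaving out single arrays gave from 3 to 8 genes for PB in hepatocytes at 24 h (without water replicate 1 and replicate 3), 1 to 809 at 14 d (PB replicate 2, water replicate 3), 0 to 11 for PB in mesenchymal cells at 24 h and 388 to 2655 at 14 d (PB replicate 1, water replicate 3). CPA gave 3763 to 4904 and 2782 to 3469 in hepatocytes, and 59 to 1059 (CPA replicates 3 and 1) and 230 to 305 in mesenchymal cells at 24 h and 6 d. The fractions gave 0 to 1 and 641 to 1828 for PB, and 724 to 1843 and 483 to 827 for CPA. The times gave 0 to 290 and 2 to 8 for PB in hepatocytes and mesenchymal cells, and 1619 to 2158 and 48 to 105 for CPA. The compounds gave 2204 to 3082 and 6 to 341, the corn oil groups 1 to 23 and 0 to 1, and the cell fractions 6780 to 7878.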

Other observations

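The hypothesis on very long genes and its test, and the check of similar arrays, were chosen after the results were seen. Other fixed lists moved as well, and none of the lists in this paragraph and the next was called with an estimated correlation (smallest adjusted p = 0.107 with an estimated correlation, growth factors in hepatocytes at 6 d of CPA). In hepatocytes at 24 h of CPA, 10 of 18 hepatocyte markers fell and 1 rose, led by Asgr1 (-0.96) and the clotting factor F2 (-0.94), and the counts adjusted over the list alone were the same. Of 15 bile acid genes 5 fell, such as Nr0b2 (-2.57), of 21 PPAR-alpha targets 7 fell and 3 rose, such as Ehhadh (-2.31) and Acot1 (3.08), and of 12 glucocorticoid receptor targets 5 fell and 1 rose (5, 7 and 3, and 6 and 1 adjusted over the list alone). Immediate early genes had 6 higher and 3 lower of 21, with Gadd45b at 2.13 and Myc at 1.58, and 4 of 14 male-biased genes fell (8 and 3, and 3 adjusted over the list alone). AhR targets had 1 higher and 1 lower of 7, inflammatory genes 3 and 3 of 34, beta-catenin targets 1 higher of 12, and matrix genes 2 lower of 21 (1 and 1, 3 and 2, 1, and 1 adjusted over the list alone). At 6 d of CPA, 6 of 11 gluconeogenesis genes fell, 8 of 25 interferon genes rose, such as Gbp2 (2.27), 6 of 34 inflammatory genes rose, such as Cxcl10 (2.99), and 6 of 21 immediate early genes fell while 1 rose (6, 8 with 1 lower, 6, and 6 and 1 adjusted over the list alone). On the same arrays the Kupffer marker mean was 6.06 against 4.85. Acute phase genes had 3 higher and 7 lower of 19, growth factors 4 and 4 of 29, the unfolded protein response 2 and 4 of 17, hepatocyte markers 1 and 7 of 18, AhR targets 2 and 1 of 7, and matrix genes 1 higher of 21 (3 and 8, 4 and 5, 2 and 4, 1 and 8, 2 and 1, and 0 adjusted over the list alone). Markers of other cells changed in few members in hepatocytes under CPA. Cholangiocyte markers had 1 higher and 2 lower of 9 at 24 h and 2 and 1 at 6 d, B cell markers 1 lower of 6 at both times, erythroid markers 2 and 1 lower of 5, Kupffer markers 1 higher of 15 at 24 h, and platelet markers 1 higher of 5 at 6 d, each with the same count adjusted over the list alone. Endothelial markers had 1 higher and 1 lower of 18 at 24 h, stellate markers 1 lower of 18 at 24 h and 1 and 1 at 6 d, and T and NK markers 1 lower of 19 at both times (1 higher, 0, 1 and 1, and 0 adjusted over the list alone). Neutrophil markers had 0 of 8 called by limma at both times (0 and 2 at an unadjusted p under 0.05).

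In mesenchymal cells at 14 d of PB, beside the lower hepatocyte markers, 4 of 12 beta-catenin targets fell (Lect2 -2.60, Oat -2.05). So did 3 of 21 PPAR-alpha targets (Ehhadh -2.65) and 3 of 12 genes listed as female-biased (Sult2a6 -2.33). Of 18 fatty acid synthesis genes 2 fell (Pklr -2.07). Adjusted over the list alone 4, 3, 3 and 7 fell. Of 13 p53 targets, 7 AhR targets and 17 CAR/PXR-type enzymes 2 each fell (2 with 1 higher, 2 and 1 adjusted over the list alone). Nrf2 targets had 1 higher and 2 lower of 15, growth factors 2 and 1 of 29, glucocorticoid targets 1 and 1 of 12, interferon genes 1 higher of 25, T and NK markers 1 higher of 19 and stellate markers 1 lower of 18 (1 and 3, 1 and 1, 1 and 0, 1, 0 and 0 adjusted over the list alone). Gluconeogenesis had 0 of 11 called by limma (3 lower adjusted over the list alone, 5 at an unadjusted p under 0.05), and no matrix, unfolded protein response, cholangiocyte, B cell, neutrophil or platelet gene was called there (2, 0, 2, 0, 1 and 0 at an unadjusted p under 0.05). At 6 d of CPA in mesenchymal cells, growth factors had 3 of 29 higher, among them Hgf (1.81), the growth factor of hepatocytes, and Gdf15 (1.73), and cholangiocyte markers had 2 of 9 higher, Epcam (1.77) and Spp1 (1.37), with the same counts adjusted over the list alone. Female-biased genes had 2 lower of 12, male-biased genes 1 higher and 1 lower of 14, and AhR targets, PPAR-alpha targets, acute phase genes and platelet markers 1 higher each (3, 1 and 1, 2 and 1, 1 and 1, 1, and 1 adjusted over the list alone). At 24 h of CPA, growth factors, AhR and PPAR-alpha targets had 1 higher each (1, 1 and 2 adjusted over the list alone), and at both times 1 stellate marker fell (1 adjusted over the list alone), Lrat (-1.64 and -1.62). At 24 h of PB in hepatocytes the acute phase list also had a call, 1 gene (1 adjusted over the list alone).

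Replicate 3 of the water and PB groups at 24 h was labelled female in both fractions. On these 4 arrays Eif2s3y, a gene of the Y chromosome, stood at 6.94 to 7.26, against 5.88 to 7.41 on the 20 arrays labelled male and 0.71 to 1.43 on the 36 other arrays labelled female. Xist, which silences an X chromosome in females, stood at 0.86 to 2.11 (0.86 to 1.77 in males, 8.18 to 9.72 in the other females), and the male P450 Cyp2c11 at 9.72 to 12.54 (9.01 to 12.68 and 2.33 to 4.04). The arrays kept their labels, so the sex term does not measure sex.

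Replicates 1 and 2 of mesenchymal CPA at 6 d and of mesenchymal water at 24 h were closer to each other than other mesenchymal pairs, with root mean square differences of 0.168 and 0.179, against 0.317 for the next closest and a median of 0.450. In hepatocytes the closest pair had 0.260. Averaging the CPA pair gave 279 genes for CPA at 6 d, 540 for the difference between fractions and 60 for that between times, and averaging the water pair gave 0, 0 and 2 for PB at 24 h, the fractions and the times.

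Among the largest falls in hepatocytes at 24 h of CPA were Esrrg, Dpyd, Pcca and Vps13b, which are very long genes by textbook knowledge. This gave the hypothesis that very long transcription units were transcribed less. A list of 53 other such genes, without those named above for their change, and its bounds were written before the list was tested, with a further camera condition added later. Of the 53, 20 fell and 0 rose, with a median log2 change of -0.28, below all 10000 random lists (lowest -0.23). Camera gave an adjusted p = 1.15e-09, and an adjusted p = 0.00142 with an estimated correlation. Plcb1 (-3.40), Ptprd (-3.35) and Magi1 (-2.99) fell most. In mesenchymal cells at 24 h of CPA the median was -0.19 with 3 falls (0.000729 with an estimated correlation). The median was also at a low percentile of random lists in hepatocytes at 6 d of CPA (-0.16, percentile 0.11, 7 falls and 2 rises, adjusted p = 0.328 with an estimated correlation) and at 14 d of PB (-0.12, percentile 0.09, 0 called by limma of 53, adjusted p = 0.188 with an estimated correlation), so a tie to CPA alone was not settled. The percentiles were 52.9 for PB in hepatocytes at 24 h, 33.5 and 45.2 for PB in mesenchymal cells, and 19.0 for CPA in mesenchymal cells at 6 d. The falls may thus have to do with transcript length or with another property these genes share, and lengths were not measured here.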
